A study of Homo sapiens with 30 samples.

How the data were processed

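Lesional skin biopsies from patients with chronic psoriasis were profiled on expression arrays, 30 arrays from 17 patients in a randomized trial of the anti-IL-17A antibody LY2439821. Groups were taken from the labels' arm, dose and week, and the arms and times used were 150 mg and placebo at weeks 0 and 2. Other doses and later biopsies were not analysed here. Replicates are patients, numbered within each arm, and the patient of every array comes from the labels. RNA was extracted and biotin labelled, per the labels' protocols. The deposited log2 values per probe set had been made with GCRMA, a background correction, normalization and summary for short oligonucleotide arrays, per the submitters' processing notes. The version and options of GCRMA are not given in the sources used here.

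The table held 22277 probe sets, and all arrays shared a floor of 2.08, where values have no order. Of these probe sets 19070 had 1 listed gene symbol, 1043 had several and 2164 had none. The platform's annotation is old, so symbols were updated through the Entrez ID with a current human RefSeq gene table used for names only, which matched 19058 probe sets. Sex-typing genes, 35 probe sets, were left out of every table. Each of 11935 genes was represented by its single-gene probe set with the highest mean over all arrays. A gene was tested if its probe set was above 3 on the log2 scale on at least 6 arrays, which kept 8292 genes and left 3643 untested. Fold changes of genes near the floor or near the brightest values are understated, and the number of arrays limits the precision. No arrays were identical (0 pairs), and the highest Spearman correlation of a pair was 0.993. The median correlation was 0.988 between arrays of 1 patient and 0.979 between patients of 1 group.

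Changes were fitted with limma 3.58.1 in R 4.3.3 on the deposited values, with 4 group means over all 30 arrays and the patient as a random block (consensus correlation 0.366), moderated by eBayes, two-sided, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. The contrasts were the change from week 0 to week 2 in each arm, the difference of the changes (the interaction of arm and week), and the arms at each week. Pairing by patient comes from the labels, and over the 13 patients with both weeks the arrays' deviations from their group means correlated with a median of 0.45, above 0.1 in 12. On simulated data with the real arrays' layout, the 150 mg change was called for 28%, 66%, 90% and 100% of genes changed by 0.5, 1, 2 and 3 on the log2 scale, with 6 unchanged genes among 148 calls. For the difference of changes the shares were 14%, 46%, 82% and 98%, with 5 among 125, and for the arms at week 2 they were 14%, 58%, 84% and 98%, with 1 among 128. The simulated genes were independent of each other, had no floor and mostly did not change. The real genes differ in all of these, so the shares and errors need not hold for them.

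Of 28 fixed gene lists, 27 had enough tested members, and the B and plasma cell list did not. They cover IL-17-induced keratinocyte genes, IL-23 and Th17 genes, other cytokines, epidermal differentiation, cell cycle, interferon responses, IL-17 signalling, housekeeping genes, stress and clock genes, and markers of the immune, stromal and appendage cell types of skin. They were tested with limma's cameraPR on the moderated statistics, with a preset inter-gene correlation of 0.01 and also with a correlation estimated per list, and with fry. Adjustment was over the 27 lists of a contrast. A list score is the mean log2 value of the tested members, and its change per patient was tested with exact sign-flip and exact arm-permutation tests (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, with plots from matplotlib 3.10.9).

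The named genes follow a rule. For each contrast these are the 12 largest rises and 12 largest falls among genes past the threshold and, within an arm, changed the same way in every patient with both weeks, or the 5 genes with the smallest p where fewer than 5 pass. Up to 4 members per list with the largest moderated statistic are added, and always IL17A, IL17F, IL22, IL23A, IL12B, IL17RA, DEFB4A, S100A7, S100A8, LCN2, CXCL1, CXCL8, CCL20, IL36G, KRT16, MKI67, FLG, LORICRIN, CD3D, LAMP3, MX1 and CXCL10. IL17F and DEFB4A had no single-gene probe set. KRT5 and KRT14 fall outside the rule and were named after their values were seen.

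The tests, lists, naming rule and the alternative settings that follow were fixed before the data were examined. These settings were no filter and a filter at 5, no patient block or the patient as a fixed effect, other probe set rules, quantile normalization, median centring, another variance model, only the compared groups, an adjusted p of 0.01, the array serial number as a covariate, other list tests and scores, and each patient left out in turn. The splits of the samples, the set of general keratinocyte genes, leaving out 3 arrays apart on the second principal component, and the fibroblast score as a covariate were chosen after seeing the data. A first version of the split tests used paired fits and was seen before it was replaced by refits of the reported model.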

Results

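Messenger RNA was measured in biopsies of lesional skin, the plaque itself, from patients with chronic psoriasis, an inflammatory disease in which the epidermis thickens and fills with immune cells. The patients took part in a randomized trial of LY2439821, an antibody that neutralizes the cytokine IL-17A, and the arms compared here received 150 mg or placebo. A biopsy came from the plaque before treatment (week 0) and after 2 weeks. The groups held 8 arrays at 150 mg and week 0, 6 at 150 mg and week 2, 8 at placebo and week 0, and 8 at placebo and week 2, from 17 patients. Both weeks were measured in 6 patients at 150 mg and in 7 at placebo. Values were log2 expression per probe set, between a floor of 2.08 and a maximum of 15.8. The median of an array lay between 5.43 and 5.75, and between 26.9% and 30.5% of an array's probe sets sat at the floor. The number of arrays limits the precision, and 8292 genes were bright enough to test.

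The first comparison asked what changed in the plaque over 2 weeks at 150 mg, before placebo is taken into account. The largest falls at 150 mg were led by genes of the fixed list of IL-17-induced keratinocyte genes. Whole biopsies do not show which cells made the RNA. S100A12, an antimicrobial calgranulin, averaged 10.54 ± 0.58 (SD, n = 8) at week 0 and 4.30 ± 1.66 (SD, n = 6) at week 2, a fall of 77.1-fold with 1 of the 6 later arrays at the floor. IL19, a cytokine made by keratinocytes, was 72-fold lower, and CXCL8, the neutrophil chemoattractant interleukin-8, was 65.9-fold lower on its brighter probe set (-2.308 on the log2 scale on the other, adjusted p = 0.043). Genes of mast cells and of the dermal matrix rose over the same 2 weeks, among them CTSG, the mast cell protease cathepsin G, by 10.1-fold and ELN, elastin, by 13.7-fold on 1 of its 2 probe sets, although the matrix list's call was lost with an estimated correlation (adjusted p = 0.338). In all, 2303 genes changed (limma, adjusted p under 0.05), 1151 upward and 1152 downward. The change was of at least 2-fold for 858 of them, 487 higher and 371 lower. Over all genes tested, 21.2% moved in the same direction in all 6 patients, against 3.125% by chance, and among the 2303, which were selected for a change in these patients, 1402 did (60.9%). The count was 1138 without the patient block and 1301 when only the arrays of the compared groups entered.

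Of 21 tested members of the IL-17-induced keratinocyte list, 19 fell, 0 rose, and 20 fell when adjusted over the list alone (limma's cameraPR, adjusted p = 6.93e-28). This call held with an estimated correlation (adjusted p = 0.00118). S100A12 changed by -6.27 on the log2 scale (SE 0.49, adjusted p = 1.73e-09), IL19 by -6.17 (SE 0.82, adjusted p = 5.69e-06) and CXCL8 by -6.04 (SE 0.76, adjusted p = 3.23e-06), each in 6 of 6 patients. TCN1, a vitamin B12 binding protein, changed by -5.28, TNIP3, an inhibitor of NF-kappa-B signalling, by -4.61 and RHCG, an ammonium transporter, by -4.53. The chemokines CCL20 and CXCL1 changed by -4.43 and -4.12, the antimicrobial LCN2 by -2.93 and the cytokine IL36G by -2.25. S100A8 fell by 0.56 from a level of 14.60. S100A7, the antimicrobial psoriasin, was at 14.33 ± 0.17 (SD, n = 8) and 14.18 ± 0.14 (SD, n = 6), and its change of -0.17 did not pass (adjusted p = 0.101). Levels near 14 lie close to the brightest value of the arrays.

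The keratins and cornified envelope genes of lesional epidermis fell in 10 of 12 tested members, and in 11 adjusted over the list alone (adjusted p = 5.68e-09). The list call was lost with an estimated correlation (adjusted p = 0.0903). KRT16, a keratin of hyperproliferative epidermis, changed by -1.66 (SE 0.25, adjusted p = 2.53e-05), the kallikreins KLK6 and KLK13 by -4.53 and -4.51, the protease TMPRSS11D by -4.67 and the cross-linking enzyme TGM1 by -2.17. SPRR2C, a small proline-rich envelope gene outside the list, changed by -5.80. Cell cycle genes fell in 37 of 40 members, and in 38 adjusted over the list alone (adjusted p = 4.42e-30). With an estimated correlation that call was lost too (adjusted p = 0.0506). CCNE1, cyclin E1, changed by -2.10 in 6 of 6 patients, and the proliferation marker MKI67 by -2.68 and UBE2C, a ubiquitin-conjugating enzyme of mitosis, by -2.35, both in 5 of 6. The genes of regular terminal differentiation rose in 3 of 8 members and in 4 adjusted over the list alone, and as a list did not pass (adjusted p = 0.15). FLG, filaggrin, rose by 0.55 (adjusted p = 0.0462), a call lost when any 1 of 11 patients was left out (150 mg replicates 1, 2, 3, 4, 6, 7 and 8 and placebo replicates 3, 4, 5 and 8, adjusted p from 0.0528 to 0.122). LORICRIN was 1.03 higher without passing (adjusted p = 0.0712). Of 12 genes known to be low in plaques, 8 rose, and 8 adjusted over the list alone, where 1 also fell (adjusted p = 0.00187, and 0.295 with an estimated correlation). Among them were the keratin KRT15, by 1.54, and the transcription factor GATA3, by 0.91.

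Genes induced by type I interferon fell in 19 of 28 members, also 19 adjusted over the list alone (adjusted p = 3.29e-09). That call was lost with an estimated correlation (adjusted p = 0.0903). OAS3 changed by -1.55 (SE 0.24, adjusted p = 2.93e-05), OASL by -2.60, the ubiquitin-like ISG15 by -1.74 and MX1 by -1.06, in 6 of 6 patients each. Before treatment this list was already lower in the 150 mg arm than in the placebo arm, with a median difference of -0.47 over its members (adjusted p = 2.77e-09, and 0.188 with an estimated correlation). The interferon gamma list had 1 riser and 1 faller among 13 members, 0 and 0 adjusted over the list alone, and did not pass (adjusted p = 0.807). Its chemokine CXCL10 had a change of -0.65 (SE 0.50, adjusted p = 0.342).

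Immune cell lists split. The T cell and cytotoxic lymphocyte list had 1 member higher and 1 lower out of 17, or 0 and 1 adjusted over the list alone, and did not pass (adjusted p = 0.807). Its median change was 0.20, its mean -0.07 and the direction of its test upward. The member that rose was CD4, at 1.05 (adjusted p = 0.0464), a call lost when any 1 of 10 patients was left out (150 mg replicates 1, 2, 3, 5, 7 and 8 and placebo replicates 1, 3, 4 and 5, adjusted p up to 0.231). The member that fell was GZMB, granzyme B, at -3.22 (SE 0.74, adjusted p = 0.00211). CD3D, a T cell receptor chain, was at 7.25 ± 0.50 (SD, n = 8) and 7.03 ± 0.93 (SD, n = 6), a change of -0.21 that did not pass (adjusted p = 0.618, SE 0.29). In the dendritic cell list 3 of 16 members fell, 1 rose, the same counts adjusted over the list alone, and the list did not pass cameraPR (adjusted p = 0.639) but passed fry in either direction (adjusted p = 0.00615). LAMP3, a marker of mature dendritic cells, changed by -1.15 (SE 0.20, adjusted p = 0.000116) and the chemokine CCL22 by -1.39, while the IgE receptor chain FCER1A rose by 1.04. The neutrophil list did not pass cameraPR (1 rose and 2 fell of 9, the same adjusted over the list alone, adjusted p = 0.129) but passed fry downward (adjusted p = 0.0099), and CXCR2, a receptor for CXCL8, changed by -2.26 (SE 0.29, adjusted p = 3.89e-06). Langerhans cell genes did not pass cameraPR (1 of 3 rose, 3 adjusted over the list alone, adjusted p = 0.129) but passed fry upward (adjusted p = 0.00153). Macrophage genes rose in 3 of 12 members, 2 adjusted over the list alone (adjusted p = 0.0254, and 0.509 with an estimated correlation), with FOLR2 at 2.01. The list of IL-23 and Th17 cytokines had no member past the threshold, 0 of 5 in either direction and 0 adjusted over the list alone (adjusted p = 0.787). IL22 was at the floor on every array, IL23A on 6 of 8 arrays at 150 mg and week 0, and IL17A averaged 2.40 there, so none of the 3 was bright enough to test. IL12B, the shared subunit of IL-12 and IL-23, averaged 3.10 ± 1.08 (SD, n = 8) before treatment and was at the floor on 5 of 6 arrays at week 2, with a change of -1.03 that did not pass (adjusted p = 0.151). The antibody target's receptor chain IL17RA had a change of -0.44 (adjusted p = 0.278). Among other inflammatory cytokines 1 of 8 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.807), and the one that fell was IL1B, 5.66-fold lower (adjusted p = 0.00668), a call lost on its other probe set (-2.174, adjusted p = 0.0548). The one that rose was IL18, at 0.40 (adjusted p = 0.0449), a call lost when any 1 of 11 patients was left out (150 mg replicates 2 to 7 and placebo replicates 3, 4, 5, 6 and 8, adjusted p from 0.0539 to 0.121).

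All 10 tested mast cell genes rose, also 10 adjusted over the list alone (adjusted p = 1.55e-06), and the call held with an estimated correlation (adjusted p = 0.0166). CTSG rose by 3.34 (SE 0.69, adjusted p = 0.000904), CMA1, chymase, by 2.88 (SE 0.55, adjusted p = 0.000354) and TPSAB1, a tryptase whose near-identical copy TPSB2 shares sequence with it, by 1.77. Fibroblast and extracellular matrix genes rose in 16 of 24 members, 19 adjusted over the list alone (adjusted p = 2.57e-06, and 0.338 with an estimated correlation). ELN rose by 3.78 (SE 0.80, adjusted p = 0.00104) on its brighter probe set and by 0.181 on the other, which did not pass (adjusted p = 0.338), and the microfibril gene MFAP4 rose by 2.74. Outside the lists, OMD, an extracellular matrix proteoglycan, rose by 3.54 and GSTA3, a glutathione transferase, by 4.14 (SE 0.77, adjusted p = 0.000272). Muscle genes rose in 6 of 9 members, 7 adjusted over the list alone (adjusted p = 0.00155, and 0.291 with an estimated correlation), with LMOD1 at 2.17 and TAGLN at 1.80. Melanocyte genes rose in 3 of 6, 5 adjusted over the list alone (adjusted p = 0.0057, and 0.295 with an estimated correlation), with OCA2 at 2.16. Endothelial genes rose in 4 of 18, also 4 adjusted over the list alone (adjusted p = 0.0181, and 0.449 with an estimated correlation), with CLDN5 at 1.09. Beside these groups, the mean score of 14 basal and general keratinocyte genes, a set chosen after the data were seen, changed by -0.241 ± 0.060 (SD, n = 6) at 150 mg, downward in 6 of 6 patients (exact sign-flip test, two-sided p = 0.0312, the smallest it allows). Within that set the basal keratins KRT5 and KRT14, near the top of the scale, had changes of 0.06 (adjusted p = 0.525) and -0.04 (adjusted p = 0.662). At week 0 the fibroblast, muscle and endothelial lists were higher in the 150 mg arm than in the placebo arm, with median differences of 0.39, 0.71 and 0.56 (adjusted p = 0.000135, 8.72e-05 and 5.34e-12, and 0.741, 0.188 and 0.0213 with an estimated correlation). With the fibroblast score as a covariate, an alternative chosen after the data were seen, 545 genes were called, with 1 of 10 mast cell, 1 of 28 interferon and 16 of 21 IL-17-induced members among them.

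The other lists did not pass cameraPR at 150 mg, while fry passed clock genes upward (adjusted p = 0.0039), IL-17 receptor and signalling (adjusted p = 0.00797) and housekeeping genes (adjusted p = 0.00614) downward, and immediate early genes in either direction (adjusted p = 0.00496). Adipocyte genes had 2 fallers of 12, or 1 adjusted over the list alone (adjusted p = 0.735), although the list's median was 0.82. The fallers were CD36, a fatty acid transporter that changed by -0.71, and ADIPOR2, whose -0.29 (adjusted p = 0.0424) is lost without any 1 of 8 patients (150 mg replicates 1, 5, 6 and 7 and placebo replicates 3, 4, 5 and 8, adjusted p from 0.0528 to 0.17). Sebaceous and epidermal lipid genes had 2 fallers of 13, also 2 adjusted over the list alone (adjusted p = 0.807). Gland genes had 1 riser of 8, also 1 adjusted over the list alone (adjusted p = 0.254), and hair follicle genes 1 of 9, also 1 (adjusted p = 0.639). Immediate early and stress genes fell in 5 of 20, also 5 adjusted over the list alone (adjusted p = 0.228), with the orphan nuclear receptor NR4A3 at -2.07. Circadian clock genes had 3 risers and 1 faller of 13, or 4 and 1 adjusted over the list alone (adjusted p = 0.0769), with the clock repressor CRY2 at 1.89 (SE 0.38, adjusted p = 0.000714). The IL-17 receptor and signalling list had 2 of each among 12, the same adjusted over the list alone (adjusted p = 0.492), with the transcription factor CEBPD at -0.83. Housekeeping genes had 1 riser and 3 fallers of 14, the same adjusted over the list alone (adjusted p = 0.488), with a median of -0.01.

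The second comparison asked what changed over 2 weeks without the antibody. At placebo no gene passed (0 of 8292, limma, smallest adjusted p = 0.999), and 161 genes had an unadjusted p under 0.05. S100A12 averaged 10.87 ± 0.73 (SD, n = 8) at week 0 and 10.72 at week 2, where its 8 values lay between 7.21 and 11.99, a change of -0.10 (SE 0.45). CXCL8 had a change of -0.51, KRT16 of -0.03, MX1 of -0.08 and CTSG of -0.98. The smallest p belonged to EXO1, a DNA repair nuclease, with a change of -0.69 (SE 0.17, adjusted p = 0.999), and DNAAF5 followed with -0.38. Among the genes called at 150 mg, the median size of the change was 0.82 at 150 mg, and the median placebo change, signed by the 150 mg direction, was 0.07. The placebo change had the same sign as the 150 mg change in 1546 of these 2303 genes. Across all tested genes the changes of the 2 arms correlated at 0.23. The preset list test passed 5 lists with small upward medians and no member past the threshold. These were regular differentiation (median 0.19), macrophages (0.37), endothelium (0.20), fibroblasts (0.20) and immediate early genes (0.20), with adjusted p of 0.0029, 0.00276, 0.00987, 0.0147 and 0.0109. With an estimated correlation none passed (adjusted p = 0.737 for 4 of them and 0.92 for fibroblasts).

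**Figure D1:**
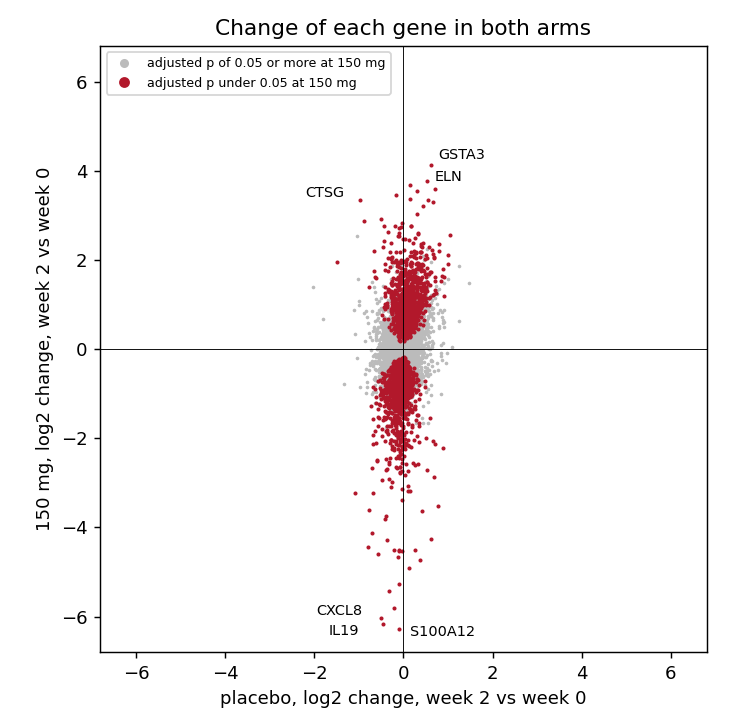
Log2 change from week 0 to week 2 of each tested gene at placebo (horizontal axis) and at 150 mg (vertical axis), with the 2303 genes called at 150 mg in red. S100A12 lies at -6.27 at 150 mg and -0.10 at placebo, and CTSG at 3.34 and -0.98.

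The third comparison asked which genes changed differently in the randomized arms. The IL-17-induced genes led the falls, with S100A12 at -6.17 (SE 0.66, adjusted p = 3.13e-06) relative to placebo, IL19 at -5.71, CXCL8 at -5.53 and TCN1 at -5.19. MMP12, a macrophage elastase, stood at -5.11, ATP12A, a proton pump, at -5.03 and CXCL13, a B cell chemoattractant, at -4.76. CTSG at 4.32 (SE 0.94, adjusted p = 0.00603) and CMA1 at 3.76 (SE 0.75, adjusted p = 0.00346) led the rises, and OMD stood at 3.24 (SE 0.67, adjusted p = 0.00424). In all, 498 genes differed, 166 toward a rise and 332 toward a fall, and 326 did so by at least 2-fold. The IL-17-induced list had 16 of 21 members lower, 20 adjusted over the list alone (adjusted p = 4.2e-28, and 0.000995 with an estimated correlation). Mast cell genes were higher in 5 of 10, 9 adjusted over the list alone (adjusted p = 5.78e-08, and 0.00427 with an estimated correlation). Cell cycle genes were lower in 26 of 40, 34 adjusted over the list alone (adjusted p = 5.56e-28, and 0.0536 with an estimated correlation), with CCNE1 at -2.16. Type I interferon genes were lower in 12 of 28, 18 adjusted over the list alone (adjusted p = 1.74e-11, and 0.0536 with an estimated correlation), with OAS3 at -1.54, and the median difference of this list between the arms at week 0 was -0.47. Lesional keratin and envelope genes were lower in 6 of 12, 8 adjusted over the list alone (adjusted p = 1.22e-08, and 0.0978 with an estimated correlation), with KRT16 at -1.63.

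Of the dendritic cell list 1 member of 16 differed, 3 adjusted over the list alone, LAMP3 at -1.41 (SE 0.27, adjusted p = 0.00275), and the list did not pass (adjusted p = 0.343). No T cell member differed, 0 of 17 and 0 adjusted over the list alone (adjusted p = 0.917), with CD3D at -0.10 (SE 0.39). Endothelial genes had 0 of 18 members differing (median 0.28, adjusted p = 0.209) and macrophage genes 0 of 12 (median 0.45, adjusted p = 0.343). Neither list passed, so their rises at 150 mg were not shown to exceed placebo. No fibroblast member differed, 0 of 24 and 0 adjusted over the list alone, although the list passed the preset test (median 0.93, adjusted p = 0.000194, and 0.538 with an estimated correlation), with ELN at 3.25 (adjusted p = 0.069). Low-in-plaque genes had 1 of 12 higher, 5 adjusted over the list alone (adjusted p = 0.000674, and 0.224 with an estimated correlation), namely GATA3 at 1.02. Melanocyte genes had 1 of 6 higher, also 1 adjusted over the list alone (adjusted p = 0.00597, and 0.299 with an estimated correlation). Muscle genes had 0 of 9, also 0 adjusted over the list alone (adjusted p = 0.00561, and 0.302 with an estimated correlation), and immediate early genes had 2 of 20 lower, 4 adjusted over the list alone (adjusted p = 0.0219, and 0.363 with an estimated correlation). CXCL1 at -3.41 (adjusted p = 0.0804), CCL20 at -3.63 (adjusted p = 0.0716) and MX1 at -0.98 (adjusted p = 0.123) did not pass. LCN2 at -2.45 passed (adjusted p = 0.0348) but not without any 1 of 8 patients (150 mg replicates 1 and 2 and placebo replicates 1, 3, 4, 5, 6 and 7, adjusted p from 0.0512 to 0.0741). The count was 130 without the patient block, 173 with the patient as a fixed effect, and 324 and 322 without placebo replicates 1 and 3.

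Per patient, the change of a list score, the mean log2 expression of its members, separated the arms in 9 of 27 lists (exact permutation test of the arm labels, two-sided, Benjamini-Hochberg adjusted over the 27). The IL-17-induced score changed by -3.28 ± 0.95 (SD, n = 6) at 150 mg and by -0.10 ± 0.73 (SD, n = 7) at placebo (exact p = 0.000583, the smallest possible, adjusted 0.00524). The mast cell score changed by 1.71 ± 0.54 and -0.30 ± 0.62, and the low-in-plaque score by 1.94 ± 1.37 and -0.02 ± 0.48, both with the same exact p and adjusted value. The interferon score changed by -1.22 ± 0.51 and 0.15 ± 0.37 (exact p = 0.00117, adjusted 0.00787), and the lesional keratin score by -2.01 ± 0.85 and -0.04 ± 0.76 (exact p = 0.00175, adjusted 0.00944). The cell cycle score changed by -1.76 ± 1.21 and -0.06 ± 0.33 and the muscle score by 1.54 ± 1.19 and 0.38 ± 0.34 (exact p = 0.00991, adjusted 0.0382 for both). The melanocyte score changed by 0.89 ± 0.56 and 0.03 ± 0.46 and the clock score by 0.63 ± 0.32 and 0.07 ± 0.41 (exact p = 0.0157, adjusted 0.0472 for both). The fibroblast score, at 1.13 ± 0.83 and 0.17 ± 0.60, did not pass (exact p = 0.0367, adjusted 0.0991), nor did the T cell score, at -0.13 ± 0.82 and 0.01 ± 0.57 (exact p = 0.729, adjusted 0.759). Within the 150 mg arm 11 scores had an exact sign-flip p under 0.05 and none passed after adjustment (smallest adjusted 0.0767), since 6 pairs allow no p below 0.03125. Leaving out 1 patient left 5 lists without 150 mg replicates 3 or 7 or placebo replicates 1, 4 or 7, the calls lost being among the cell cycle, muscle, melanocyte and clock scores. With the median over members as the score, the lesional keratin, melanocyte and muscle calls were lost, and with median centring, quantile normalization or members scaled to unit SD the clock call was lost, as was the melanocyte call with unit SD.

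**Figure D2:**
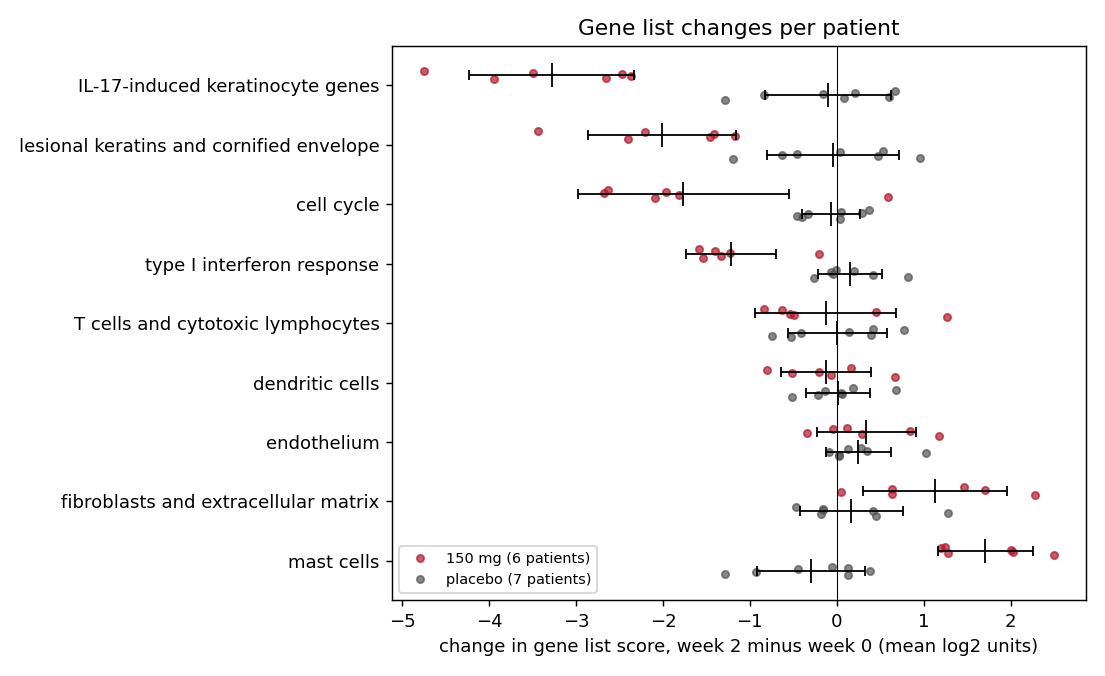
Change of the list score from week 0 to week 2 in each patient (points, mean log2 units), with mean and SD (bars), for 9 lists in the 6 patients at 150 mg (red) and 7 at placebo (grey). The IL-17-induced score averages -3.28 and -0.10, the mast cell score 1.71 and -0.30, and the T cell score -0.13 and 0.01.

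The fourth comparison set the arms side by side before treatment. At week 0 the leading genes stood at similar levels, S100A12 at 10.54 ± 0.58 at 150 mg and 10.87 ± 0.73 at placebo, CXCL8 at 9.87 ± 1.54 and 9.70 ± 1.90, and KRT16 at 14.32 ± 0.20 and 14.44 ± 0.24 (SD, n = 8 in each arm). No gene passed (0 of 8292, limma, smallest adjusted p = 0.997), and 225 genes had an unadjusted p under 0.05. The smallest p belonged to NTAQ1, a glutamine amidohydrolase, with a difference of -0.81 (SE 0.21, adjusted p = 0.997). Endothelial genes were higher at 150 mg as a list, by a median of 0.56 over 18 members with none past the threshold (adjusted p = 5.34e-12, and 0.0213 with an estimated correlation). Another 6 lists passed the preset test and not the estimated one, namely type I interferon (median -0.47), fibroblasts (0.39), muscle (0.71), lesional keratins (-0.38), T cells (0.19) and dendritic cells (0.31). Their adjusted p with an estimated correlation were 0.188, 0.741, 0.188, 0.79, 0.79 and 0.585.

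The fifth comparison set the arms side by side after 2 weeks. S100A12 was lower at 150 mg, by -6.48 on the log2 scale (SE 0.59, adjusted p = 7.06e-08), as were IL19 (-5.91), SPRR2C (-5.69), TCN1 (-5.58) and RSAD2, the interferon-induced antiviral viperin (-4.88). CILP, a cartilage matrix protein gene, was higher by 4.46 (SE 1.27, adjusted p = 0.0114), PLN, the muscle gene phospholamban, by 3.85 and ELN by 3.73. At week 0 the difference had been -1.33 for RSAD2 and 1.14 for PLN, neither passing. In all, 2171 genes differed (limma), 1061 higher and 1110 lower at 150 mg, and 1060 by at least 2-fold. With the fibroblast score as a covariate the count was 483. IL-17-induced genes were lower in 18 of 21, 19 adjusted over the list alone (adjusted p = 1.07e-20, and 0.0122 with an estimated correlation). Type I interferon genes were lower in 23 of 28, also 23 adjusted over the list alone (adjusted p = 9.1e-16, and 0.0136 with an estimated correlation), against a week 0 difference of -0.47. Mast cell genes were higher in 9 of 10, also 9 adjusted over the list alone (adjusted p = 1.16e-06, and 0.0136 with an estimated correlation). Another 8 lists passed the preset test and not the estimated one. Cell cycle genes were lower in 35 of 40 (38 adjusted over the list alone, adjusted p = 0.0953 with an estimated correlation) and lesional keratins in 10 of 12 (11 adjusted over the list alone, adjusted p = 0.0953 with an estimated correlation). Neutrophil genes were lower in 2 of 9 (2 adjusted over the list alone, adjusted p = 0.0953 with an estimated correlation). Fibroblast genes were higher in 14 of 24 (17 adjusted over the list alone, adjusted p = 0.361 with an estimated correlation) and muscle genes in 7 of 9 (8 adjusted over the list alone, adjusted p = 0.0953 with an estimated correlation). Endothelial genes were higher in 9 of 18 (10 adjusted over the list alone), melanocyte genes in 6 of 6 (6 adjusted over the list alone) and low-in-plaque genes in 5 of 12 (8 adjusted over the list alone), with adjusted p of 0.179, 0.179 and 0.205 with an estimated correlation. Of these, the endothelial, fibroblast and muscle lists had also been higher at 150 mg at week 0 in the preset test, with no member passing, and with an estimated correlation only the endothelial call held (adjusted p = 0.0213, against 0.741 and 0.188). The lesional keratin list had likewise been lower at 150 mg at week 0 in the preset test (median -0.38, adjusted p = 0.0491, and 0.79 with an estimated correlation).

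**Figure D3:**
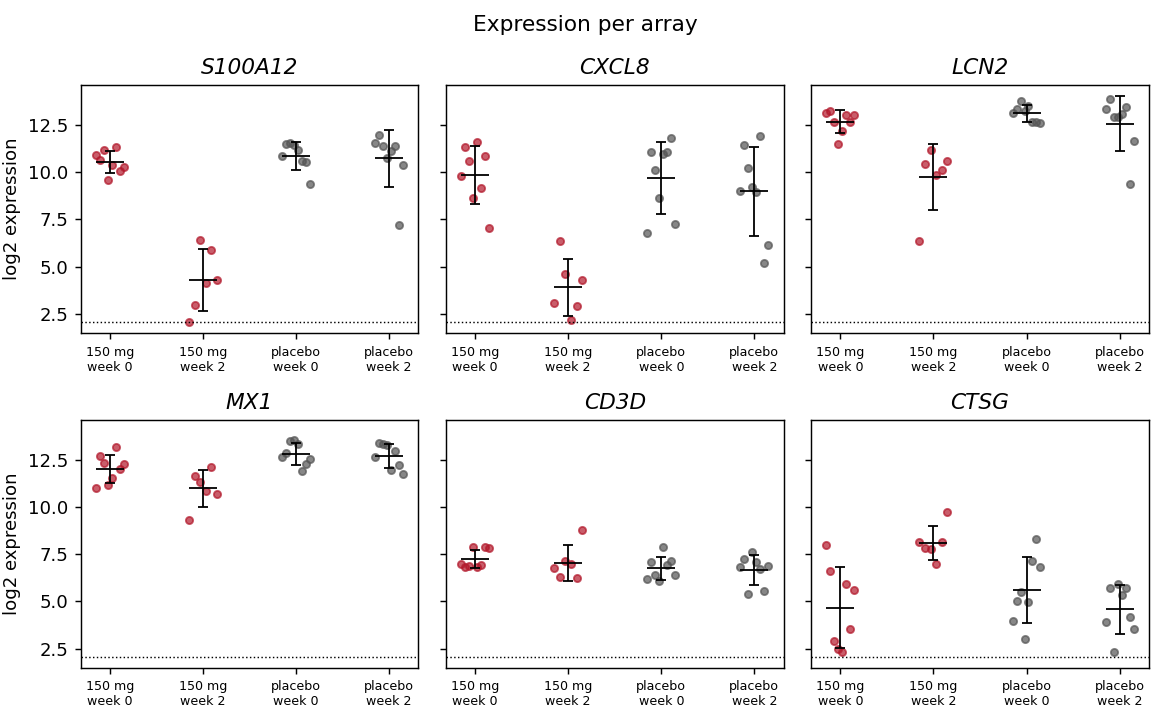
Log2 expression of 6 genes on each array (points) in the 4 groups, with mean and SD (bars) and the floor of 2.08 (dotted line). S100A12 at 150 mg and week 2 lies between 2.08 and 6.43, and between 7.21 and 11.99 at placebo and week 2, while CD3D overlaps in all groups.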

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

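The splits and the tests of explanations in this part were chosen after the result was seen except 2, the general keratinocyte score for the fibroblast rise and its comparison with the interferon score, and the gene set of that score was itself chosen after the data were seen.

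In 4 of the 54 sets of score changes, 1 patient lay far from the others of the arm. The gap to the nearest patient was 0.734 of the whole range for cell cycle genes at 150 mg, 0.739 for type I interferon genes at 150 mg, 0.731 for sebaceous and epidermal lipid genes at 150 mg, and 0.603 for endothelial genes at placebo. Chance gives such a gap in about 1 of 20 sets. The change differed between the arms for 498 genes by the test of the difference itself. Probe sets that the gene comparisons left out also changed at 150 mg. Of those with several listed symbols 189 of 690 tested passed (27.4%), and of those with none 173 of 871 (19.9%), beside 27.8% of the named genes. At placebo 0 of either kind passed (limma), with 15 and 17 at an unadjusted p under 0.05.

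Other splits of the samples were refitted with the same model. There were 64 ways to swap the weeks within the patients at 150 mg. Only 1 gave as many calls, the real one, with 2303 against 1484 in the highest other. This argues against chance without excluding it. The week 0 arrays of patients without a second biopsy kept their label, which favours the real order, and the swap of every pair mirrors it. For the difference of changes 1 of 100 splits gave as many, again the real one, with 498 against 0 in the highest other. For the arms at week 2 it was also 1 of 100, with 2171 against 1074. Chance is argued against for both, although for the difference the patients with 1 biopsy kept their arm. At placebo 37 of 100 splits gave as many genes at an unadjusted p under 0.05 as the 161 found, and for the arms at week 0 63 of 100 gave as many as the 225 found, so chance cannot be excluded for either. The highest other splits there, at 1319 and 1588 genes, are several times the real counts, which points to a structure of the samples whose source was not tested, while the medians of the other splits were 97 and 299.

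Mast cell genes rose at 150 mg in 10 of 10 members and fibroblast genes in 16 of 24. The fibroblast list call was lost with an estimated correlation (adjusted p = 0.338), and 0 of 24 members differed from placebo. The general keratinocyte score changed by -0.241 (SD 0.060, downward in 6 of 6 patients, exact p = 0.0312), as a smaller epidermal share of the biopsy needs. Within it, KRT5 and KRT14, near the top of the scale, did not pass. The housekeeping score also fell in 6 of 6 patients, at -0.067 (SD 0.039, exact p = 0.0312). A small fall within the 150 mg arm is thus not particular to keratinocyte genes. Relative to placebo, however, the keratinocyte score changed by -0.222 (exact permutation p = 0.00291) and the housekeeping score by -0.030 (exact permutation p = 0.427). Such a share is only a possible part of the fibroblast rise. A smaller epidermal share as the whole cause would raise endothelial genes alike. The mast cell score rose beyond the endothelial one by 1.368 (SD 0.507) and the fibroblast score by 0.788 (SD 0.394). Each gap held in 6 of 6 patients (exact sign-flip p = 0.0312, the smallest possible and not adjusted over the tests of this part). On this measure such a share as the whole cause is argued against. The fibroblast gap is weaker ground, since the scores compared lay at unlike levels. At 150 mg and week 0 the fibroblast score was 10.298 ± 0.828 (SD, n = 8), against 6.970 ± 0.672 for the endothelial one. The endothelial list may not be a neutral measure of dermis, however. At week 0 it was already higher at 150 mg than at placebo (median difference 0.56, cameraPR adjusted p = 0.0213 with an estimated correlation). The estimate for its member SELE stood at -2.493 to -1.545 relative to placebo with 1 patient left out in turn. SELE did not pass, since 0 of 18 endothelial members differed from placebo, also 0 adjusted over the list alone. In the change at 150 mg alone 4 of the 18 endothelial members rose and 0 fell. A normalization that pushed unchanged genes up is argued against by the mast cell gap, within the same limits of the endothelial list. Such a push acts on genes by their level, and the week 0 level at 150 mg was 6.206 ± 1.034 (SD, n = 8) for the mast cell score and 6.970 ± 0.672 for the endothelial one. With the fibroblast score as a covariate 1 of 10 mast cell genes passed, CMA1 at 2.19 (SE 0.62) from 2.88 (SE 0.55), and the median change of the 10 went from 1.683 (median SE 0.386) to 1.214 (median SE 0.436), so calls ended through smaller changes and larger errors together, in a fit whose covariate itself changed with treatment. An effect of the antibody on these cells and an uneven share of the dermal layers in the biopsies both stay open.

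Type I interferon genes fell at 150 mg in 19 of 28 members, a list call lost with an estimated correlation (adjusted p = 0.0903), and 2 of the 3 other explanations tested could not be excluded. A loss of T cells that carry such RNA cannot be told apart. The change of the T cell score exceeded that of the interferon score by a mean of 1.088 (SD 1.059), in 5 of 6 patients (exact sign-flip p = 0.0625). The dendritic cell score changed by -0.124 ± 0.517 (SD, n = 6) and was not set against the interferon score, so a loss of dendritic cells was not tested. A smaller epidermal share cannot be excluded either, although the keratinocyte score changed by only -0.241. The interferon score lay below it by a mean of -0.975 (SD 0.514), in 5 of 6 patients (exact sign-flip p = 0.0625). In that keratinocyte set KRT5 and KRT14 sit near the top of the scale, where changes are understated. Regression of unequal arms towards each other is argued against, since the 150 mg score began at -0.586 relative to placebo and the arms then moved further apart, by -1.369 (exact permutation p = 0.00117). With the fibroblast score as a covariate 1 of 28 members passed, OAS3 at -1.31 (SE 0.27) from -1.55 (SE 0.24), and the median went from -1.234 (median SE 0.340) to -0.700 (median SE 0.392), so the calls ended mainly through smaller changes. An effect of the antibody stays open beside these.

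T cell genes showed no fall as a list, which a larger dermal share could produce by offsetting a loss of T cells. Set against the endothelial score, the T cell score changed by -0.470 (SD 0.386) and lay above it in 1 of 6 patients (exact p = 0.0625), so a loss that was offset and no loss cannot be told apart with 6 patients. The T cell genes were also dim on average, with a score of 4.827 ± 0.365 (SD, n = 8) at 150 mg and week 0. Of 29 members on the array 17 were bright enough to test, and a fall of genes near the floor is understated. A p that misses the threshold does not show that T cell numbers were unchanged.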

How the results depend on the processing

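The settings without the arrays apart on the second component and with the fibroblast score as a covariate were chosen after the results were seen. Over the other settings with all patients, added ones included, 2547 values of single genes kept their direction and side of the threshold, 252 became weaker, 28 stronger and 17 reversed. With 1 patient left out in turn 4347 kept both, 229 became weaker, 50 stronger and 15 reversed. Of the list scores 228 stayed the same under the other settings, 7 became weaker, 2 stronger and 6 moved by more than their spread. Without the patient block 1138 genes changed at 150 mg and 130 differed in their change, and 4 lists passed at week 0. With the patient as a fixed effect, the paired block, 173 differed in their change. In both fits the count of differences of at least 2-fold was also lower by over 1.5 times. Over all settings 17 counts of genes moved that far with all patients, and 2 with 1 patient left out. With only the compared groups 1301 genes changed at 150 mg. At an adjusted p of 0.01 the counts were 1163 at 150 mg, 158 for the difference and 1019 for the arms at week 2, by construction lower. With the fibroblast score as a covariate they were 545, 143 and 483. Without a cause tested for any of them, reversals were these, all of genes that did not pass. Without the block the difference of changes of IL17RA was -0.032. With the patient as a fixed effect the 150 mg change was -0.092 for CCR6 and -0.112 for POU2AF1. With quantile normalization it was -0.037 for POU2AF1, and the difference of IL17RA was -0.033. Without the arrays apart the differences were 0.146 for CCR6, 0.012 for KRT1, -0.135 for CD14, 0.212 for POU2AF1, -0.231 for SCGB1D2 and -0.153 for IL17RA. With the covariate the 150 mg changes were -0.126 for KLRB1, -0.214 for CCR6, -0.105 for POU2AF1, -0.089 for FABP4 and -0.303 for LPL, and the difference was -0.043 for AHR. Of the list tests, 11, 5, 10, 7 and 11 passed for the 150 mg change, the placebo change, the difference, week 0 and week 2, and with an estimated correlation 2, 0, 2, 1 and 3. Fry in one direction passed 15, 0, 8, 0 and 15 in the same order, and in either direction 13, 0, 3, 0 and 12. At 150 mg these included lists that did not pass cameraPR, namely neutrophils, Langerhans cells, clock, IL-17 receptor and signalling and housekeeping genes in one direction. Leaving out 1 patient in turn gave 1616 to 2358 genes at 150 mg, 322 to 640 for the difference, 1651 to 2585 at week 2, 0 at placebo and 0 at week 0 (limma), and 5 to 11 list scores apart between the arms. It also turned the 150 mg change of CCR6 (-0.471 to 0.342) and POU2AF1 (-0.125 to 0.261) and the difference of POU2AF1 (-0.290 to 0.096), IL17RA (-0.184 to 0.204) and CD3D (-0.344 to 0.040), and the score differences of T cells (-0.413 to 0.007), endothelium (-0.075 to 0.231) and IL-17 receptor and signalling (-0.058 to 0.030), none passing. The 150 mg score change also crossed 0 for T cells (-0.407 to 0.012), dendritic cells (-0.284 to 0.011) and hair follicle genes (-0.078 to 0.599). Values near the floor and near the brightest signal limit what can be read from dim cytokine and T cell genes and from the S100 genes.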

Other observations

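The comparison without the arrays apart on the second component and the gene values below were chosen after the results were seen.

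Within the mast cell rise at 150 mg, genes of granule storage and mediator synthesis moved with the proteases. CPA3, a carboxypeptidase of mast cell granules, rose by 2.76 (adjusted p = 0.0132), HPGDS, a prostaglandin D synthase, by 1.62, SLC18A2, a vesicular monoamine transporter, by 1.49 and HDC, the enzyme that makes histamine, by 1.28. The receptor KIT and the transcription factor GATA2 rose by 0.93 and 0.99. The chemokine CXCL13 changed by -4.50 (SE 0.68, adjusted p = 2.93e-05), CHAC1, an enzyme that degrades glutathione, by -4.26 and VNN3P, a vanin family member, by -5.42 (SE 0.47, adjusted p = 1.32e-08). Among the housekeeping genes, HPRT1, a purine salvage enzyme, changed by -0.82 (SE 0.13, adjusted p = 6.24e-05), and by -0.71 relative to placebo (adjusted p = 0.0172).

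At week 2 the adipocyte list had 2 members higher and 2 lower of 12 at 150 mg, the same adjusted over the list alone, and did not pass (adjusted p = 0.27). LPL, lipoprotein lipase, stood 3.37 higher (adjusted p = 0.0288), against 1.96 at week 0, and CIDEC, a lipid droplet protein, 3.17 higher (adjusted p = 0.0398), while ADIPOR2 (-0.38, adjusted p = 0.0295) and CD36 (-0.99, adjusted p = 0.00253) were lower. In the difference of changes 0 of the 12 members were higher and 1 was lower, so LPL and CIDEC did not pass there. Among muscle genes ACTC1, cardiac actin, stood 3.84 higher, against 2.23 at week 0, and LMOD1 3.66 higher, against 1.77, and none of these week 0 differences passed (limma, 0 genes, 225 at an unadjusted p under 0.05).

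The first and second principal components held 30.8% and 17.7% of the variance, and 3 arrays lay more than 3 scaled median absolute deviations from the median on the second, 1 at 150 mg and week 0 and 2 at placebo and week 2. Without them 2349 genes changed at 150 mg, 0 at placebo, 581 differed in their change, 0 differed at week 0 and 2618 at week 2. All 10 mast cell genes, 10 fibroblast genes, 20 interferon genes in the downward direction, 18 IL-17-induced genes and 38 cell cycle genes then passed at 150 mg.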
